A study of Homo sapiens with 2 samples.

How the data were processed

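Exosomal miRNA of U87MG delta EGFR glioblastoma cells was measured on Toray 3D-Gene human miRNA arrays, 1 for non-treated cells and 1 for cells given boron neutron capture therapy (BNCT). Per the labels, cells grew in medium with exosome-depleted serum, RNA was extracted with a miRNeasy kit and total RNA was labelled with Cy5. The labels give 1 treatment text for both samples, so it was taken to describe the BNCT sample, and the group of each sample came from its treatment label. The human probes are named by miRBase name and ID. Names were used as the files give them, and 16 probe names hold several miRNAs.

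Per the file headers, the deposited scanner files hold median spot intensity at 635 nm, with lines fitted between 3 scanner gains, a background median per spot and a flag per gain. The r2 of the line between the gains 1 and 2 was 0.910 on the control array and 0.998 on the BNCT array. The values had not been scaled between arrays, and 2 miRNA spots on the control array, miR-3136-3p and miR-410-3p, carried a failure flag and were left out there. The authors' processed values are intensities on a linear scale. Every listed value equals the spot median minus a constant divided by a factor, with a largest residual of 1.23e-06. The constants, 258.1 and 254.9, lie at the mean of the blank spots without the top and bottom 5%, and the factors, 1.25 and 1.54, set the median of the listed values to 25 on each array, 761 values in control and 957 in BNCT. This settles scale, centring and direction. The software used for it is not given in the sources used here.

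Spots were read in R 4.3.3, background-corrected with limma 3.58.1 (nec, which fits the normexp model on the blank spots, offset 50) and put on the log2 scale. Control spots were then left out and the 2632 miRNA probes, 1 spot each, were quantile-normalized between the arrays. A miRNA was detected where its spot median exceeded the mean + 2 SD of the array's blank spots without the top and bottom 5%, which gave limits of 272.0 and 267.5 units. The design fixed before the data were examined placed the scanner's local background column first and the blank spots second. That column was found to follow the spots' own signal. Its median at the spike control spots was 20539 and 26767 units, its slope on the spot median of detected probes was 0.608 and 0.875, and it was at or above the spot median at 11 and 77 detected probes. The blank spots were therefore used, a choice made after seeing the files and before differences were computed, and the counts with the column, and its values for some of the named miRNAs, are given in the report.

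Differences are BNCT minus control on the log2 scale. With 1 array per group no test was run, and the rule of size was 2-fold. With so few arrays precision is limited by their number. The spot error combines the SD of the blank spots without the top and bottom 5% and the spike control CV (4.70% and 8.03%). That SD was 6.93 and 6.27 units, against 8.66 and 7.60 over all blanks. Carried to the log2 scale, the spot error had a median of 0.157. It covers neither cultures nor slides. For a miRNA detected on 1 array, a lower bound was computed against the higher of the dim array's lowest detected level and the dim probe's own level. List medians were given for lists with 3 or more members detected on both arrays, with their percentile among 10000 random lists matched on level in 10 bins. The 17 lists, 12 for pathways and 5 for other cell types, held 200 names, of which 195 were on the array. Shares have 95% Wilson intervals.

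The rule for named miRNAs, fixed before the data were examined, took the 10 largest differences in each direction, the 5 largest in each direction among probes brighter than the median of those detected on both arrays, the 5 brightest probes per array, the 3 largest bounds per array among miRNAs detected on 1 array, up to 4 detected members of each list with the largest differences, any member of a list with 5 or fewer detected members, and miR-21-5p. The list members with the smallest differences are not all named. Spot errors, the counts at 0.5 and at 3 spot errors, the simulations, the split by arm and the limits from spots without a probe were added after the files were seen. The alternatives fixed beforehand were plain blank subtraction, no background correction, an offset of 16, scaling to the median or the 75th percentile of shared probes, cyclic loess, no normalization, a limit at 5 SD, no detection filter and the authors' values. Added alternatives were the scanner's background column, spike scaling, blank subtraction with a shared median, a limit from spots without a probe and a common limit.

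The procedure was tested on simulated arrays for this comparison, made from the 2632 probes with spot noise of 8 units and 6%. In 10 runs without change no probe reached 2-fold, and the SD of differences was 0.161 to 0.172. With 200 probes changed by 2-, 3- and 4-fold in blank-subtracted brightness, the direction was right for 99.5%, 99.5% and 98.9% of those detected on both arrays, and 3.63%, 33.2% and 67.2% reached 2-fold. The changed probes were drawn only from those above a floor of brightness, and 193, 187 and 180 of them were detected on both arrays. These shares therefore do not cover the dimmest detected probes. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.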

Results

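The series asked how the miRNA content of exosomes, the small vesicles that cells release into their medium, compares between glioblastoma cells given boron neutron capture therapy (BNCT) and cells left untreated. The cells were U87MG delta EGFR, a derivative of the U87MG glioblastoma line named for a truncated epidermal growth factor receptor. In BNCT a boron compound is loaded into cells and thermal neutrons then split the boron, which releases short-range particles. Here the BNCT cells were held for 2 hours with 25 ppm of a boronophenylalanine-fructose complex and irradiated. Their medium was collected on day 3 after irradiation. The labels do not say separately whether the control cells got the compound or sham handling, or when their medium was collected. Compound, irradiation, handling and time of collection therefore cannot be told apart. Each group had 1 array with 1 colour (Cy5) and 2632 miRNA probes, so there are no replicates, no test and no p-value, and the 2 arrays are compared by sizes alone. The sample titles name exosomes, while the extraction protocol in the labels speaks of RNA from cells. Signal was low: the brightest miRNA spot read 1183.7 scanner units on the control array and 1877.1 on the BNCT array, over blank spots with means of 258.1 and 254.9. The median miRNA above the detection limit lay 31.5 units over the blanks on the control array and 38.6 on the BNCT array.

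The miRNA profile of the 2 arrays was similar, and no miRNA detected on both differed 2-fold under the main processing. The brightest probe on both arrays was miR-6743-5p. It was followed on the control array by miR-3960, miR-6085, miR-6787-5p and miR-5787, and on the BNCT array by miR-6787-5p, miR-4454, miR-6125 and miR-6085. After normalization miR-3960 differed by -0.18 on the log2 scale (BNCT minus control, spot error 0.13), miR-5787 by -0.19 (spot error 0.13) and miR-4454 by 0.12 (spot error 0.13). Among the known glial miRNAs, miR-24-3p, which is transcribed together with miR-23a and miR-27a, was the bright one, at 620.0 units on the control array and 915.6 on the BNCT array, a normalized difference of 0.14 (spot error 0.13). Its partner miR-27a-3p was under the limit on both arrays (268.9 and 252.0 units), and miR-23a-3p on the BNCT array. With the scanner's own background column miR-24-3p differed by -1.79, miR-4454 by -1.97, miR-6787-5p by -2.04, miR-6085 by -2.02, miR-6743-5p by -0.62, miR-3960 by -0.57 and miR-6125 by -0.59, and miR-5787 turned to 0.21. Without normalization miR-3960 and miR-5787 turned to 0.53 and 0.45, with spike scaling to 0.82 and 0.73, and in the authors' values to 0.26 and 0.17. Across the 630 probes detected on both arrays the differences had a median of -0.02 and an SD of 0.22, with Pearson r = 0.964 and Spearman rho = 0.921 between arrays. These correlations are across probes, which are not independent replicates. A median this small follows largely from quantile normalization, which gives both arrays the same distribution of levels. Without normalization the median was 0.49, and with plain blank subtraction the SD was 0.50.

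The miRNAs highest in BNCT relative to control were miR-1202 (0.75, spot error 0.19), miR-7150 (0.73, spot error 0.18) and miR-6088 (0.68, spot error 0.16). They were followed by miR-4433b-3p at 0.66, miR-10396b-5p at 0.63, miR-3150a-3p at 0.62 and miR-1914-3p at 0.61, and then by miR-4436b-3p, miR-4638-5p and miR-4776-5p at 0.59 each. miR-1202 read 272.3 units on the control array, against a limit of 272.0. Of these 10, only miR-6088 and miR-10396b-5p were above the 5 SD limits on both arrays. The sizes depended on the setting. miR-1202 was 0.16 with the scanner's background column, 0.23 without background correction, 1.90 with plain subtraction and 2.24 in the authors' values, and miR-4433b-3p, miR-1914-3p and miR-4436b-3p were 0.09, 0.11 and 0.10 with that column. Among probes brighter than the median miR-6885-5p at 0.59 and miR-3196 at 0.56 (-0.20 with the scanner's background column) joined miR-10396b-5p, miR-6088 and miR-1914-3p. The miRNA lowest in BNCT was miR-508-5p, a member of the X-linked miR-506 family, at -0.82 (spot error 0.16). It was followed by miR-6872-3p at -0.66, miR-6070 at -0.65, miR-1470 at -0.62, miR-6777-3p at -0.58, miR-6813-5p at -0.56, miR-6752-3p and miR-8059 at -0.55, miR-6499-5p at -0.54 and miR-614 at -0.52. Of these 10, only miR-508-5p, miR-8059 and miR-614 were above the 5 SD limits on both arrays. miR-1470 and miR-6777-3p read 269.6 and 269.4 units on the BNCT array, against a limit of 267.5. Among probes brighter than the median miR-10400-3p at -0.48, miR-375-5p at -0.45 (0.35 with that column) and miR-10396a-5p at -0.44 were lower, beside miR-8059 and miR-614. The sign of all 5 bright lower miRNAs turned without normalization and with scaling to the spike control spots, since their raw brightness was nearly equal (miR-8059 read 449.8 on the control array and 453.5 on the BNCT array). Of the 10 miRNAs with the largest lower differences, 2 turned without normalization, 5 with spike scaling and 3 with the scanner's own background column, miR-6777-3p to 0.51, miR-6813-5p to 0.35 and miR-6499-5p to 0.11. Of the 10 with the largest higher differences, miR-3150a-3p turned to -0.23 and miR-4776-5p to -0.12 with that column and none turned under the other 10 settings.

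By count, 12 miRNAs were higher and 11 lower by 0.5 or more on the log2 scale, and 16 higher and 11 lower lay beyond 3 spot errors. The split at 0.5 followed the scaling, with 8 higher and 77 lower with median scaling, 5 and 99 with the 75th percentile, 303 and 0 without normalization, 472 and 0 with spike scaling and 263 and 51 in the authors' values. In 10 simulated pairs of arrays without any change, 1 to 4 probes reached 0.5 in either direction, 1 to 5 lay beyond 3 spot errors, and the largest difference was 0.692. These simulated arrays detected 798 to 836 probes in control and 1132 to 1179 in BNCT, more than the real ones, so they are a rough yardstick. Of the miRNAs detected on both arrays, miR-1202, miR-7150 and miR-508-5p lay beyond that largest simulated value. Where 200 other probes were simulated to change 2-, 3- or 4-fold, unchanged probes reached differences of 0.774, 1.188 and 1.354, and 6, 17 and 29 of them passed 0.5. The spot error covers only noise within an array, and each array had its own slide, so slide and group cannot be told apart. The 2-fold counts depended on the background correction and the scaling. They stayed at 0 higher and 0 lower with median, 75th percentile and cyclic loess scaling and without background correction. Otherwise, plain subtraction of the blanks gave 16 higher and 24 lower, the scanner's background column 9 and 24, no normalization 18 and 0, spike scaling 113 and 0, blank subtraction with a shared median 8 and 66, and the authors' processed values 72 and 15. The count of 0 does not exclude changes, because the offset of 50 shrinks them. Among simulated changes, drawn from brighter probes and detected on both arrays, 3.63% of those 2-fold in blank-subtracted brightness reached the 2-fold line. Of such 4-fold changes 67.2% did.

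**Figure D1:**
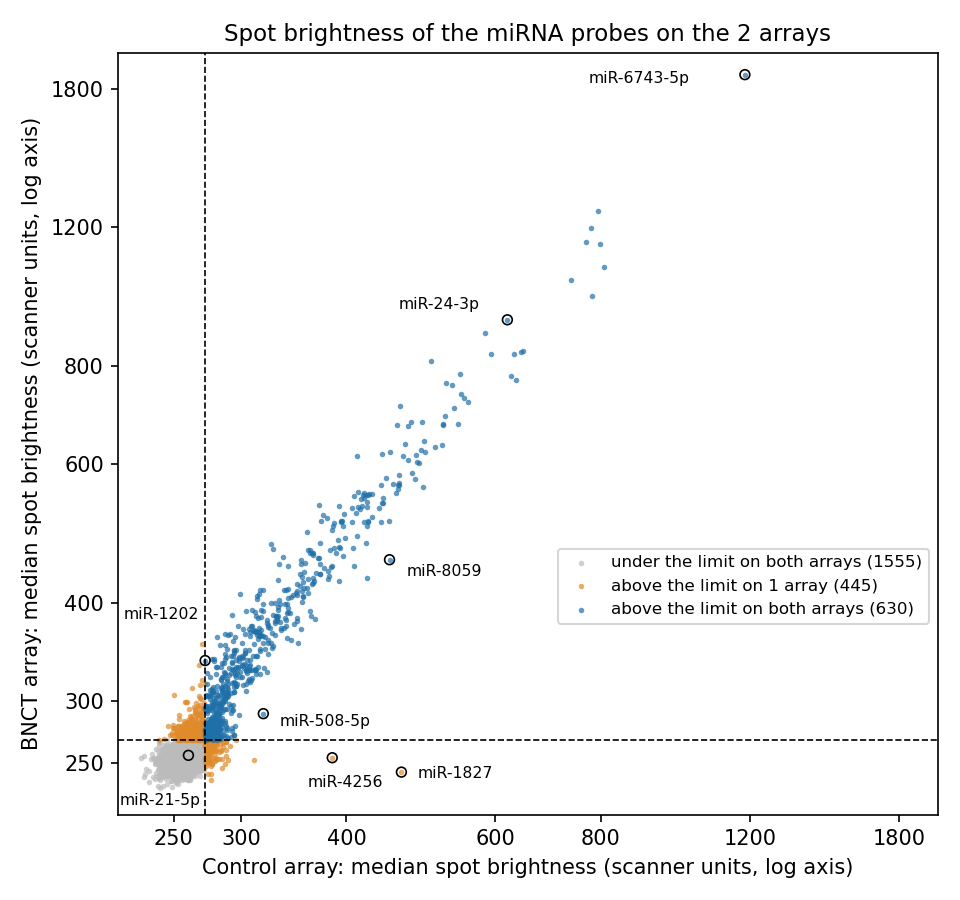
Median spot brightness of each miRNA probe without a failure flag on the control array (x axis) and on the BNCT array (y axis), both in scanner units on log axes, with 1 point per probe and dashed lines at the detection limits of 272.0 and 267.5. The 630 probes above both limits follow 1 band with miR-6743-5p at its top, miR-21-5p lies under both limits, and miR-1827 and miR-4256 are bright on the control array alone.

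More miRNAs were detected on the BNCT array than on the control array. On the control array 752 of 2632 miRNA probes (28.6%, 95% Wilson interval 26.9 to 30.3) were above the mean of the blank spots + 2 SD, and on the BNCT array 953 (36.2%, 34.4 to 38.1). Detection on the control array alone was found for 122 probes, and on the BNCT array alone for 323. The clearest miRNAs on the control array alone were miR-1827, at 464.6 units against 243.5 (at least 5.21-fold higher in control), miR-4256, at 384.9 against 253.9 (at least 3.48-fold), and miR-378a-5p, at 311.1 against 252.3 (with a bound just under 2-fold). On the BNCT array alone the clearest were miR-1275, at 354.1 units against 269.9 (at least 1.87-fold higher in BNCT), miR-4253 (at least 1.63-fold) and miR-6507-5p (at least 1.47-fold). Each bound sets the brighter array's normalized level against the higher of the dim array's lowest detected level and the dim probe's own level. Each rests on 1 spot per array, so a faulty spot cannot be told from a difference. The miR-410-3p spot, left out for its failure flag, also read high on the control array alone (578.4 units against 250.6). The bounds hold for the main setting. The lowest over the other settings were 1.98-fold for miR-1827, 1.58-fold for miR-4256 and 1.24-fold for miR-378a-5p, all without background correction. With the scanner's background column miR-1275 had no bound above 1, and the bounds of miR-4253 and miR-6507-5p were at most 1.07-fold. Of the 323 probes detected on the BNCT array alone, 175 had a bound above 1 in the main setting, and 0 had one of 2-fold or more. On the control array alone all 122 had a bound above 1, and 2 had one of 2-fold or more. That all 122 lay above 1 was fixed by the procedure. Quantile normalization gives both arrays the same levels, and more probes were detected on the BNCT array, so its lowest detected level lay lower. The contrast between the arrays in bounds above 1 therefore says nothing about the miRNAs. The intervals cover counting of probes only, and 17 of the 312 blank spots on the control array and 16 on the BNCT array were themselves above the limit. Of 112 spots that carry no probe, 112 and 110 were above it, with means of 301.3 and 289.0 units, which is brighter than most of the detected list members named here. With limits at 5 SD the counts were 356 and 524, and with limits from spots that carry no probe 235 and 404.

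Most miRNAs of the lists chosen for glioblastoma, radiation and vesicle biology were at the level of the blanks. Of 143 such miRNAs on the array, 16 were detected on the control array, 23 on the BNCT array and 9 on both, and none differed 2-fold under the main processing. Under other settings some did. In the authors' values miR-1260a was 1.04, and with the scanner's background column miR-24-3p was -1.79 and miR-4454 -1.97. With spike scaling these were 1.06, 1.08 and 1.09. miR-21-5p, the most studied oncogenic miRNA of glioblastoma vesicles, was below the limit on both arrays, at 260.2 units on the control array and 255.7 on the BNCT array. Among 19 growth-promoting glioblastoma miRNAs, miR-155-5p alone was detected, and on the BNCT array only (275.1 units). Among 9 let-7 family members, which repress growth genes, let-7d-5p was detected, on the BNCT array only (252.8 and 271.7), and among 13 members of the MYC-driven miR-17 cluster and its paralogs miR-92a-3p, also on the BNCT array only (259.5 and 275.1). The fold bounds of miR-155-5p, let-7d-5p and miR-92a-3p were 1.02, 0.99 and 1.02.

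Of 16 miRNAs tied to p53 and DNA damage, 2 were detected on each array. The p53 target miR-34a-5p was above the limit on the control array only (276.8 units in control, 237.6 in BNCT), miR-1246 on the BNCT array only (259.7 and 282.0), and miR-145-5p on both (difference 0.03, spot error 0.21, but -0.38 with median scaling). Of 15 miRNAs reported after ionising radiation, 1 was detected on the control array and 4 on the BNCT array, the latter being miR-1246, miR-29a-3p, miR-30c-5p and miR-155-5p. The fold bounds of miR-1246 and miR-155-5p were 1.10 and 1.02. The miR-29 and miR-30 families had 0 of 8 members detected on the control array and 3 on the BNCT array, namely miR-29a-3p, miR-30c-5p and miR-30e-5p. The fold bounds of these 3 were 1.04, 0.97 and 0.98, and over all probes 28.6% and 36.2% were detected on the 2 arrays. Of 16 growth-restraining glioblastoma miRNAs 4 were detected on each array, with miR-491-5p (0.16, spot error 0.18, but -0.22 with the scanner's background column and -0.04 with median scaling) and miR-145-5p on both, miR-34a-5p and miR-205-5p on the control array only, and miR-124-3p and miR-181b-5p on the BNCT array only. Of 9 inflammatory miRNAs, miR-155-5p, miR-132-3p and miR-181b-5p were detected, on the BNCT array only. The fold bounds of these inflammatory miRNAs were 1.02, 0.96 and 0.97, and 36.2% of all probes were detected on that array. Among all of these the brightest was miR-491-5p in BNCT, at 304.9 units, followed by miR-1246.

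Of 16 miRNAs abundant in glial and mesenchymal lines, miR-24-3p was detected on both arrays, miR-23a-3p (280.5 units in control, 259.0 in BNCT) and miR-23b-3p (280.6 and 259.6) on the control array only, and miR-29a-3p on the BNCT array only. The hypoxia and stress list had 2 of 11 members detected on each array, with miR-24-3p on both and miR-210-5p on the BNCT array only (270.8 and 282.4, fold bound 1.11). The other arm of that hairpin, miR-210-3p, was under the limit on both arrays (259.2 and 263.1). The imprinted 14q32 cluster, expressed in brain and placenta, had 5 of 36 members detected on each array. Of its members, miR-495-3p (289.5 and 252.3) and miR-323a-3p (287.7 and 249.6) were above the limit on the control array only, miR-134-5p (260.9 and 281.9) and miR-411-5p (248.5 and 273.2) on the BNCT array only. miRBase entries that overlap other non-coding RNA genes, such as tRNA genes, were the list with the most signal. Of 7 on the array 4 were detected on both, miR-4454 (778.4 and 1197.8), miR-1260b (449.0 and 507.4), miR-3648 and miR-1260a. Their median difference was 0.06, at the 73.2 percentile of 10000 random lists of matched level, and it ranged from -0.17 with the scanner's background column to 0.96 with spike scaling, with 0.54 in the authors' values.

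**Figure D2:**
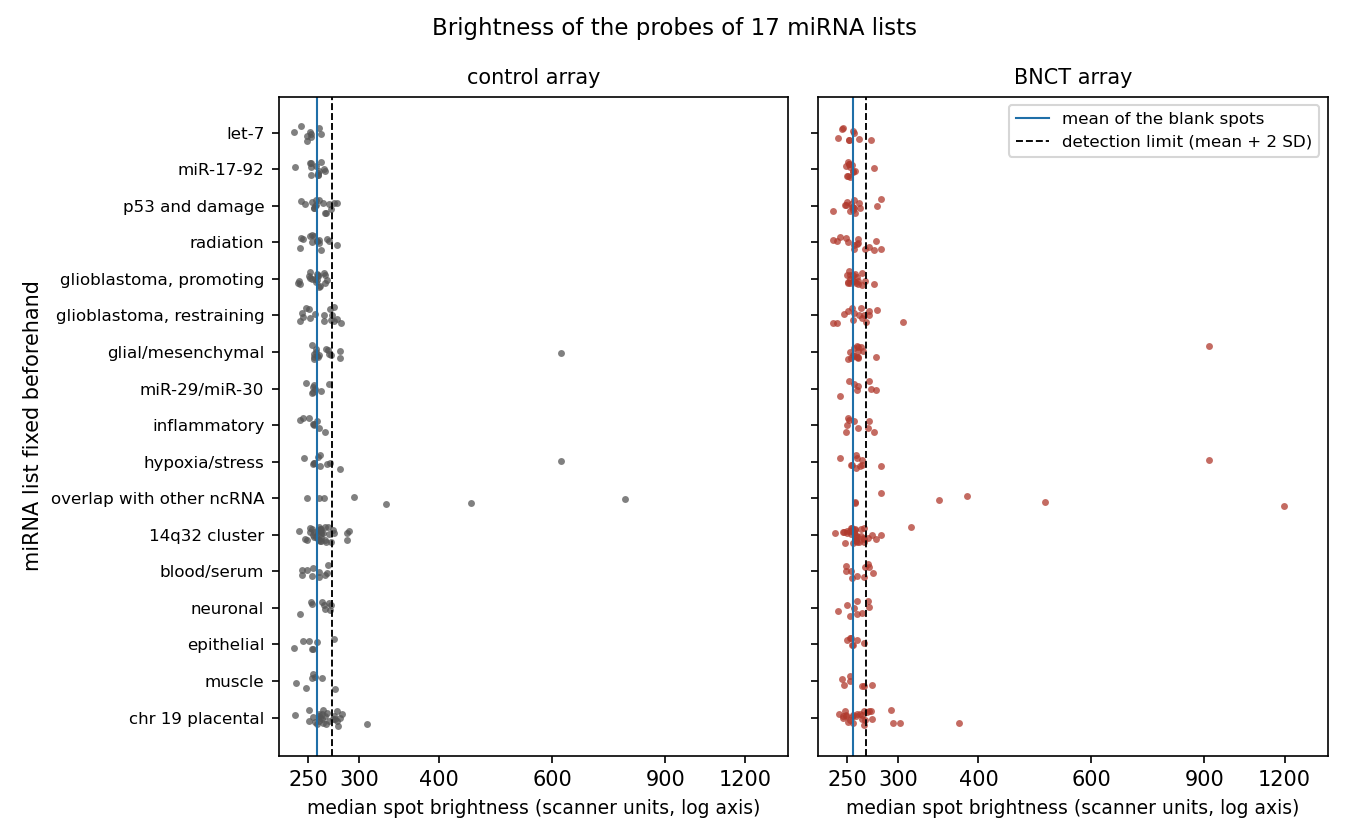
Median spot brightness (x axis, scanner units, log axis) of every probe of the 17 miRNA lists (rows), except the flagged miR-410-3p, on the control array and the BNCT array, with the mean of the blank spots as a solid line and the detection limit as a dashed line. Most points lie near the blanks, and miR-24-3p, 4 of the 7 entries that overlap other non-coding RNA and the placental miR-498-5p stand apart.

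Most markers of other cell types were near or below the limit on both arrays, and the placental miR-498-5p, singled out after its values were seen, was the brightest of them (308.6 units in control, 373.5 in BNCT, difference 0.21, spot error 0.15). Blood and serum miRNAs had 0 of 10 detected on the control array and 3 on the BNCT array, miR-144-3p at 268.9 units, miR-486-5p at 270.5 and miR-223-3p at 273.8. Their fold bounds were 0.96, 0.97 and 1.01. Neuronal miRNAs had 0 and 2 of 9 detected, miR-124-3p at 269.7 units and miR-132-3p at 269.2 in BNCT. miR-124-3p was no brighter there than in control, where it read 270.9 units under a higher limit. Of 7 epithelial miRNAs miR-205-5p was detected, in control (274.5), and of 7 muscle miRNAs miR-133a-3p was detected on both arrays (274.7 and 272.5). The placental cluster of chromosome 19 had 9 of 27 detected in control, 8 in BNCT and 5 on both. The median difference of those 5 was 0.04, at the 82.2 percentile of matched random lists, and it ranged from -0.27 with 75th percentile scaling to 0.60 with spike scaling, with 0.42 in the authors' values. Its members miR-523-3p (301.5 units in BNCT), miR-521 (278.0 in control) and miR-525-5p (276.8 in control) were detected on 1 array, and miR-518e-3p on both with a difference of -0.27 (spot error 0.20) that turned to 0.43 with the scanner's background column and 0.22 with spike scaling.

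High-numbered miRNAs, the later entries of miRBase, carried most of the signal. Of 1695 probes for miRNAs numbered 1000 and over, 528 were detected on both arrays (31.2%, 95% Wilson interval 28.99 to 33.40), against 102 of 937 numbered under 1000, let-7 included (10.9%, 9.05 to 13.0). The median difference between BNCT and control was -0.02 for the first class and -0.05 for the second, and neither class held a 2-fold difference under the main processing. Both did in the authors' values, with miR-1202 at 2.24 and miR-508-5p at -1.15 among them.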

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

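The tests with the spike control spots and with S-Probe1014 were chosen only after the counts of detected probes were seen, and the common limit is a setting added after the files were seen. A control probe outside the miRNA set, S-Probe1014, was picked out because its signal was higher on the BNCT array. Its 8 spots averaged 419.0 ± 9.48 units (SD over spots) on the control array and 503.5 ± 17.6 on the BNCT array, while S-Probe28 averaged 271.5 on the BNCT array, above its limit, and 265.2 on the control array. What this probe detects is not stated in the sources used here.

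It was weighed together with the larger number of miRNAs detected on the BNCT array, 953 against 752. A lower detection limit on that array is argued against as the only cause. With 1 common limit above the blank mean the BNCT count fell from 953 to 897, still 1.193 times the control count. A brighter scan of that array is argued against only at the brightness of the spike control spots. After blank subtraction these were dimmer there, at 0.824 of the control array. Their means were 24893 to 42123 units, far above any miRNA spot, so they do not settle the miRNA range. Also open is 1 brightness factor shared by all signal that comes from the RNA sample, which may reflect more labelled RNA on the BNCT array. S-Probe1014 was 1.545 times as bright after blank subtraction (standard error 0.0504), just under the middle range of 1.55 to 1.96 of the brighter miRNAs. An allowance of 2 standard errors, set after this value was seen, leaves the factor undecided where a rule without it would have excluded it. Other values go against a single factor without deciding it, with a ratio of 0.789 at the spots without a probe, whose signal has no stated source, and a median ratio of 1.47 for the dimmer miRNAs, which lie close to the limit, against 1.73 for the brighter ones. An effect of BNCT on exosome yield or miRNA content is likewise open and untested, since each group had 1 array on its own slide.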

How the results depend on the processing

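The scanner's background column, spike scaling, blank subtraction with a shared median, the limit from spots without a probe and the common limit were chosen after seeing the data. For 2-fold differences the main counts were 0 higher and 0 lower. They were 16 and 24 with plain blank subtraction, 5 and 5 with an offset of 16, 18 and 0 without normalization, 9 and 24 with the scanner's background column, 113 and 0 with spike scaling, 8 and 66 with blank subtraction and a shared median, 72 and 15 in the authors' values, and 0 and 3 over all probes with no detection filter. They stayed at 0 and 0 with no background correction, median, 75th percentile and cyclic loess scaling, and the 2 stricter limits. In simulated arrays without change, plain subtraction alone gave 19 to 32 such probes. The median of all differences was 0.49 without normalization, 0.77 with spike scaling, 0.41 in the authors' values and -0.23 with blank subtraction and a shared median; otherwise the cause of these shifts was not tested.

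Detected probes in control and BNCT fell from 752 and 953 to 356 and 524 at 5 SD and to 235 and 404 with spots without a probe, and those on 1 array only from 122 and 323 to 8 and 176, and to 3 and 172. A higher limit lowers the totals by construction, and for the counts on 1 array the cause was not tested. The direction was kept at every limit, with 752 and 897 at the common limit and 761 and 957 in the authors' list. The median of the entries that overlap other non-coding RNA, 0.06, became 0.68 without normalization, -0.17 with the scanner's background column, 0.96 with spike scaling, -0.10 with blank subtraction and a shared median and 0.54 in the authors' values. That of the chromosome 19 cluster, 0.04, became -0.23 with median scaling, -0.27 with the 75th percentile, 0.31 without normalization, 0.60 with spike scaling, -0.22 with blank subtraction and a shared median and 0.42 in the authors' values; the cause was not tested.

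Of 40 named miRNAs detected on both arrays, 0 moved by a spot error or more with cyclic loess, 20 with median scaling and 40 with spike scaling. The 6 named lower bounds moved by a spot error or more under each of the 10 settings that give one. Lists with fewer than 3 members detected on both arrays have no median, nor has the chromosome 19 cluster at 5 SD, and detection filters do not change a single miRNA's value. No paired analysis was possible because each group had 1 array and leaving one out leaves no comparison. Signal over background limits the rest. The median detected miRNA lay 31.5 and 38.6 units over blanks with SDs of 6.93 and 6.27 (top and bottom 5% left out).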

Other observations

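Both tests on the authors' 2-fold split were chosen, and the second replaced by another, after the result was seen, and the test on arms was written before its result. Only a few miRNAs numbered under 1000 were bright, and these were chosen here after their values were seen. Some came from hairpins whose other arm lay near the detection limits, such as miR-149-3p and miR-365a-5p. miR-149-5p read 263.1 units in control and 271.4 in BNCT. The shared probe of miR-365a-3p and miR-365b-3p read 263.9 and 269.2. The other arms were not compared for the full set. Of 146 probes over 100 units above the blanks on both arrays, 17 were numbered under 1000, of which 9 were higher and 8 lower in BNCT after quantile normalization, while all 17 were brighter on the BNCT array before it. Beside miR-24-3p they included miR-296-3p (545.5 units in control, 781.6 in BNCT, difference 0.11, spot error 0.13), miR-149-3p (459.3 and 673.2, difference 0.29, spot error 0.13), miR-920 (476.7 and 678.7, difference 0.21, spot error 0.13), miR-365a-5p (439.0 and 506.7, difference -0.20, spot error 0.12) and miR-762 (422.8 and 500.2, difference -0.17, spot error 0.12), and the largest difference among them was that of miR-614, -0.52.

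Bright high-numbered miRNAs stood beside let-7 and miR-21-5p probes at the level of the blanks. A candidate explanation is that signal follows the sequence of the arm rather than the amount of the hairpin's miRNA. Among miR-6500 to miR-6899, 135 of 194 5p arms (69.6%) and 35 of 193 3p arms (18.1%) were detected on both arrays, a difference of 51.5 percentage points. Among numbers under 1000 the arms differed by 5.02 points, at 13.1% and 8.09%, low shares that leave less room for a gap. This contrast is what arm sequence would give, but selective loading of 1 arm would give it too, and base composition was not tested. The small gap under 1000 does not show that the arm mattered less there. It compares shares, and the brighter arm can be 5p in some hairpins and 3p in others, as with the bright miR-365a-5p and miR-149-3p. No group of the design bears on the contrast, so no biological explanation was tested.

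The authors' values held 72 miRNAs 2-fold higher and 15 lower in BNCT, which was 82.8% higher. One candidate explanation is that the median was taken over each array's own list, 761 and 957 values: with the median of shared probes 10.8% of the 2-fold probes were higher, but this shifts every probe by the same -0.63, so it decides nothing about the cause. A second is a difference that depends on brightness: with the median trend over 10 level bins removed and the overall median kept, the share was 94.7%, against 66.7% with that median set to 0, so most stayed higher and the choice of centre moved the share. Neither test decides, and an effect of BNCT on single miRNAs is untested with 1 array per group.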
